A study of Rattus norvegicus with 4 samples.

How the data were processed

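MicroRNA was profiled in extracellular vesicles (EVs) of 2 rat cell lines in 4 libraries that fall into 3 groups. PC12, described by the labels as a catecholamine cell, is a rat line from a pheochromocytoma, a tumour of the adrenal medulla, and gave 1 library titled EVu and 1 titled EVd. The labels do not say what the letters u and d stand for, so both are used here as names. RMT1, described as a breast cancer cell line, gave 2 libraries. Per the labels' protocols, RNA was extracted with QIAzol and the miRNeasy Mini kit and made into small RNA libraries with the QIAseq miRNA kit, and the series' design text states that RMT1 vesicles were collected by ultracentrifugation. Nothing in the labels says that the RMT1 libraries came from separate cultures, or that the libraries of both cell lines were prepared together. Cell line therefore cannot be told apart from any preparation batch.

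The first table holds PC12 only. Per the file headers its values are raw counts, and the authors listed 594 names with whole-number counts, of which 528 are microRNAs and 66 are piRNAs, a class of small RNA best known from the germ line. The counts sum to 512244 in EVu and 386957 in EVd. Beside them stand the authors' log2 normalized values, which equal the log2 of each count times 1 factor per library, 0.886 for EVu and 1.15 for EVd, and the authors' log2 fold change of EVd over EVu. The second table holds log2 normalized values that the authors scaled over all 4 libraries together, for 762 microRNA names, with 0 where nothing was counted. On the linear scale 100% of the values above 0 lay within 0.1 of a whole multiple of 1 step per library, and dividing by that step recovered counts that sum to 799224 and 716940 in the RMT1 libraries, 436840 in EVu and 338233 in EVd. The authors' comparisons in that table are differences of these log2 values, with no p-values. The submitters' processing notes name the genome build mm10, a mouse build, while the names carry the rat prefix and the loci are given without a build. The aligner, the counting program and the scaling method are not given in the sources used here, nor whether counts are reads or unique molecules. Coordinates are printed as the first table gives them, with the build unnamed.

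Both tables hold the same PC12 libraries, and their counts differ. Over 465 shared microRNA names, 133 had EVu counts within 20% of each other, 141 were at 0 in the table of all 4 libraries, and those 141 names held 2.98% of the EVu counts of the PC12 table. In EVd, 136 names lay within 20%, 156 were at 0, and these held 3.73% of the counts. Values of such names are uncertain for this reason, and some have many counts, such as miR-3587 with 1235 and 1169 in the PC12 table and 0 in the other. EVd was compared with EVu on the PC12 table. Shares of libraries and the comparison of cell lines used the table of all 4 libraries.

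For each library the share of counts was computed for every microRNA and for each family, with exact Clopper-Pearson binomial 95% intervals. A count of 0 allows up to 3 counts. All intervals and floors cover counting error only. EVd was set against EVu as the log2 ratio of CPM, that is counts scaled by the library total, with a pseudocount of 1 CPM, with an exact binomial 95% interval of the ratio of shares. With 1 library per group no test was made, and microRNAs were counted at a fold of 2 among those with a mean of at least 10 counts. For each of 25 microRNA lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on abundance in 10 bins. Such percentiles describe these 2 libraries and are no test of a condition.

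RMT1 EV was compared with PC12 EV by limma with a mean-variance trend, on the authors' log2 values of the 278 microRNAs whose linear values averaged at least 10. The design had 3 groups and the contrast was RMT1 EV minus the mean of EVu and EVd. Only the RMT1 pair gives a residual spread, with 1 degree of freedom, to which limma added 0.547 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method at 0.05. The plan made before the data were examined was edgeR on raw counts if both cell lines had them, and no test otherwise. The table of all 4 libraries holds jointly scaled log2 values, so limma was used in its place and edgeR and DESeq2 were run on the recovered counts as alternatives. P-values measure only the spread between these samples, which may be technical. Where a microRNA had 0 counts in both libraries of a cell line, the fold is a lower bound with a floor of 3 counts over that cell line, given in the authors' scaling or from pooled shares. For most other named microRNAs with few counts in 1 cell line the ratio of pooled shares is given in place of the fitted value or beside it, since the limma error leaves out counting error. With 1 to 3 counts, the ratio of pooled shares is given with its counting interval. Pooled shares are scaled by library totals and not by the authors' factors.

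In simulated counts with the totals of these libraries and the spread of the RMT1 pair, each name had 1 mean share in both cell lines. Of all names, 200 were then changed by a fold of 2 or 4. The limma step was run on the 291 simulated names that passed the minimum. It called 34 (94.4%) of 36 names changed by a fold of 2, 43 (100%) of 43 changed by a fold of 4, and 9 (4.25%) of 212 unchanged names. Among the calls, these 9 false ones stood beside 34 and 43 true ones. Their share of the calls was therefore larger than the 0.05 that the adjusted p threshold allows on average. The simulation held no shift of let-7 and set no name to 0 in 1 cell line, so it does not give the share of false calls in the real data. The percentile step was tested on the 472 microRNAs of the EVd and EVu comparison with lists of 12, and placed 2% of random lists and 97% of lists shifted by 1 log2 unit outside the central 95%.

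The microRNAs named were fixed by rule before the data were examined. They are the 10 most abundant of each library (by the mean for RMT1), the 12 highest and 12 lowest log2 ratios of EVd over EVu, the most abundant members of each list, the 12 largest fitted folds each way past the threshold between cell lines, and the 5 largest folds each way in the authors' tables. Any other named microRNA was chosen after its values were seen. Alternatives were other pseudocounts, minimums and folds, TMM and median-of-ratios scaling, other tests, and leaving out each RMT1 library. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. piRNA names entered the library totals, the authors' counts and a count by fold of their own, and no microRNA count or list.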

Results

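The microRNA cargo of EVs was counted in 2 libraries of RMT1, a rat breast cancer line, and in 1 library each of PC12 EVu and PC12 EVd, from a rat catecholamine-producing tumour line. In the table of all 4 libraries the total was 799224 and 716940 counts for RMT1 EV 1 and 2, 436840 for EVu and 338233 for EVd. There 3 counts stand for a share of 0.000375%, 0.000418%, 0.000687% and 0.000887%, in the same order. PC12 EVu and EVd have no replicates. The RMT1 libraries resembled each other closely: across 177 microRNAs with a mean of at least 10 counts, which are not independent replicates, Pearson's r of log2 CPM was 0.977 and the median absolute log2 difference was 0.16. They still differed by more than sampling noise, with a chi-square of 6.84 per degree of freedom. They were counted as 2 samples because the labels list them as such, and this spread does not show that they came from separate cultures. EVu and EVd differed more, with a median absolute log2 difference of 0.52 across 246 microRNAs.

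The first question was which microRNAs fill the vesicles of each line. RMT1 EVs were dominated by let-7, the family that restrains growth-promoting genes such as Lin28 and Hmga2 and is kept low in stem cells. The family took 69.1% ± 0.260 (SD, n = 2) of RMT1 counts, against 23% in EVu (95% exact binomial interval 22.9% to 23.1%) and 21.6% in EVd (21.5% to 21.8%). In RMT1, let-7c-5p alone held 22.8% ± 0.278 and let-7b-5p 18.6% ± 0.0989, followed by let-7f-5p at 6.76% ± 0.0658, let-7i-5p at 6.57% ± 0.0806, let-7a-5p at 5.62% ± 0.0581 and let-7g-5p at 5.26% ± 0.0770 (SD, n = 2 each). Members of let-7 differ by few bases, so the split between them is uncertain, while the family sum is not affected. miR-31a-5p, a microRNA studied in breast cancer spread, held 6.36% ± 0.270 of RMT1 counts. It had 3 counts in EVu and 0 in EVd, but 34 and 42 in the PC12 table of the same libraries, so its low PC12 share is known only roughly.

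PC12 EVs were led by miR-16-5p, a ubiquitous microRNA that slows the cell cycle and is also abundant in red blood cells. It held 14.2% of EVu (14.1% to 14.3%) and 9.24% of EVd (9.14% to 9.34%), and 5.05% ± 0.119 (SD, n = 2) of RMT1 counts. let-7i-5p, let-7c-5p and let-7f-5p followed in EVu at 5.60%, 4.94% and 4.72%. In EVd the next was miR-322-5p, the rodent counterpart of human miR-424, at 6.81% (6.73% to 6.90%), which held only 1.17% of EVu (1.14% to 1.21%) and 0.0949% ± 0.00579 of RMT1. miR-125b-5p, abundant in neurons, held 3.67% of EVu and 5.37% of EVd, and miR-29a-3p, which represses collagen genes, 3.57% and 5.11%. miR-27b-3p held 3.11% and 4.23% of the PC12 libraries but 0.0108% ± 0.000664 of RMT1. miR-191a-5p and miR-93-5p were among the leading microRNAs of both lines, with 2.40% and 2.01% of RMT1, 3.92% and 3.86% of EVu, and 4.26% and 2.33% of EVd.

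**Figure D1:**
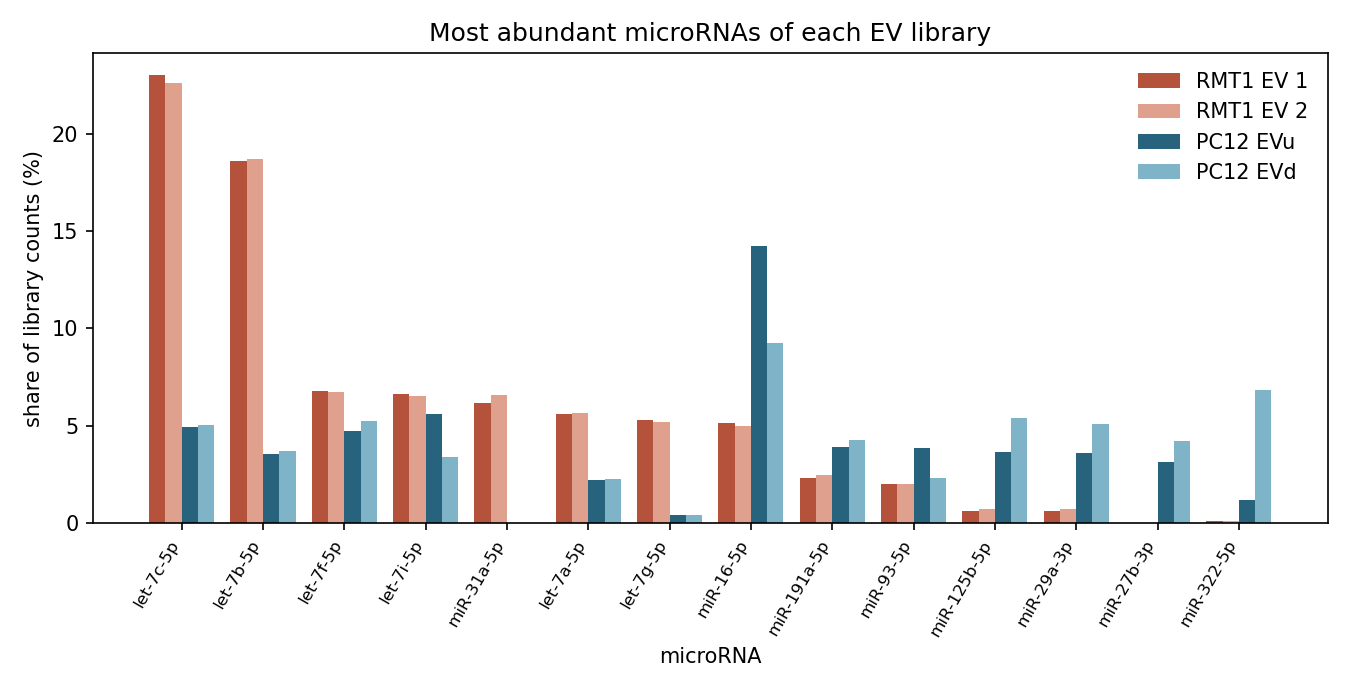
Bars give the share of library counts, in percent, of the 10 most abundant microRNAs of each library, for 2 RMT1 EV libraries and 1 library each of PC12 EVu and EVd. let-7c-5p and let-7b-5p lead RMT1 EV at means of 22.8% and 18.6%, while miR-16-5p leads EVu at 14.2% and EVd at 9.24%.

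The largest differences between EVd and EVu included microRNAs of a pair of X-linked clusters that were higher in EVd and blood-cell microRNAs that were lower. miR-221-3p and miR-222-3p, neighbours on chromosome X that repress the cell-cycle inhibitor p27 and respond to growth factors, were 25.1-fold and 12.9-fold higher in EVd. Their log2 ratios were 4.61 (95% counting interval 3.97 to 5.42), from 18 and 341 counts, and 3.59 (2.56 to 5.05), from 7 and 68 counts. The other arms of these hairpins moved less. miR-222-5p was at 0.55 (0.14 to 0.96) from 96 and 106 counts, and miR-221-5p at 0.11 (-1.33 to 1.52) from 11 and 9. miR-322-5p, the most abundant of the changed microRNAs, was 5.79-fold higher, with 5400 counts in EVu and 23620 in EVd. At the other end miR-486 and miR-451-5p of red blood cells were 14.4-fold and 10.6-fold lower, and miR-142-3p and miR-223-3p of white blood cells 12.1-fold and 10.2-fold lower. Of 472 microRNAs with a mean of at least 10 counts, 65 were at least 2-fold higher and 33 at least 2-fold lower. In the other deposited table of the same libraries 26 of 246 were higher and 32 lower, so the balance depended on the table. With 1 library per group these differences have no replicate check.

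miR-322-5p lies on chromosome X at 152773490 to 152773511 on the plus strand, and its neighbours were higher with it. miR-503-5p (152773788 to 152773810) had a log2 ratio of 2.18 (2.08 to 2.28), miR-503-3p 2.33 (1.97 to 2.72), miR-351-5p (152774528 to 152774552) 2.15 (2.08 to 2.22) and miR-322-3p 2.13 (1.67 to 2.63). Of the 10 microRNA names counted within that cluster, 9 had intervals wholly above 0, and the exception was miR-450b-3p at 0.74 (-0.20 to 1.73). The other microRNAs among the 12 highest were miR-5132-3p at 2.47, miR-504 at 2.45, miR-874-5p at 2.25, miR-336-3p at 2.16 and miR-19b-1-5p at 2.13. These 5 are uncertain, since each had at most 2 counts per library in the other deposited table of the same libraries, where miR-504 and miR-874-5p had the opposite direction.

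The 12 lowest also held miR-142-5p at -2.80 (-4.12 to -1.81), miR-144-3p, a red cell microRNA made beside miR-451, at -2.36 (-4.15 to -1.09), and the liver microRNA miR-122-5p at -1.88 (-3.06 to -0.92). The other arm of miR-144, miR-144-5p, was at 0.03 (-0.89 to 0.92) in the PC12 table but had 10 and 0 counts in the other, and miR-122-3p was at -1.54 (-2.37 to -0.81). miR-192-3p, of liver and gut, was at -1.93 (-2.72 to -1.24) from 102 and 20 counts, but had only 3 and 1 in the other deposited table, with a log2 ratio of -0.99. miR-210-3p, which is induced by hypoxia, was 3.32-fold lower, with 861 counts in EVu and 196 in EVd. miR-190a-5p, made from an intron of the talin gene Tln2, was 3.03-fold lower, with 2242 and 559 counts. miR-3574, at -3.08, lies at the locus of miR-210-3p on the opposite strand (chromosome 1, 221125917 to 221125938), and the deposited tables do not say how strand was used in counting. It and miR-3561-5p, at -2.05, had 0 counts in the other table.

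By list, 6 of the 25 lay outside the central 95% of random lists, where 1.25 would by chance if names varied independently. Many lists hold both arms of a hairpin or members of 1 cluster, and some share members. More lists than that can therefore fall outside without a shared response. The cluster of miR-221 and miR-222 stood at percentile 99.98, with 2 of its 4 names at least 2-fold higher. The neurotrophin-responsive list, microRNAs reported to follow nerve growth factor, stood at percentile 98.9 with a median of 0.55, but with a minimum mean of 100 it lay inside the central range. Of its 21 names 5 were at least 2-fold higher and 1 lower, and its most abundant members, miR-29a-3p and miR-29c-3p, were at 0.50 (0.47 to 0.53) and 0.27 (0.23 to 0.31). It holds miR-221 and miR-222 too. The blood and serum list had a median of -0.60 (percentile 0.26), with 6 of 16 names at least 2-fold lower and 0 higher. Its most abundant members were miR-16-5p at -0.64 (-0.66 to -0.62) and miR-25-3p at -1.37 (-1.44 to -1.29), against 0.67 (0.53 to 0.82) for miR-185-5p.

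The liver list had a median of -1.54 (percentile 0.03) over 5 names, 3 of them at least 2-fold lower. Its most abundant members did not move, with miR-192-5p at 0.05 (-0.06 to 0.16) and miR-194-5p at -0.01 (-0.27 to 0.24), and with a minimum mean of 100 the percentile was 71.1. The lymphoid and myeloid list stood at percentile 2.87, with 3 of 9 names at least 2-fold lower. All 11 names of the miR-30 family lay within a fold of 2 and 10 were below 0 (median -0.57, percentile 0.655). miR-30a-5p, at -0.92 (-0.97 to -0.88), went with most of them and miR-30c-5p, at 0.49 (0.42 to 0.55), did not, though it was at -0.63 in the other deposited table. The family of miR-15, miR-16 and miR-195 had a median of -0.64 (percentile 0.655), although miR-322-5p, which shares its seed sequence, is a member. In the other deposited table the liver list stood at percentile 62.5, the miR-30 family at 3.62 and the miR-16 family at 2.88, all inside the central range. Lists inside that range in the PC12 table but outside it there were lymphoid and myeloid (0.025), the miR-17 clusters (1.48), hypoxia (2.11) and the miR-29 family (97.9), which made 7 lists outside there. miR-451, miR-144, miR-486, miR-122, miR-223 and miR-142, microRNAs of blood and liver, together reached 1738 CPM in EVu, 121 in EVd, and 63.8 and 57.2 in the RMT1 libraries, in the table of all 4 libraries.

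**Figure D2:**
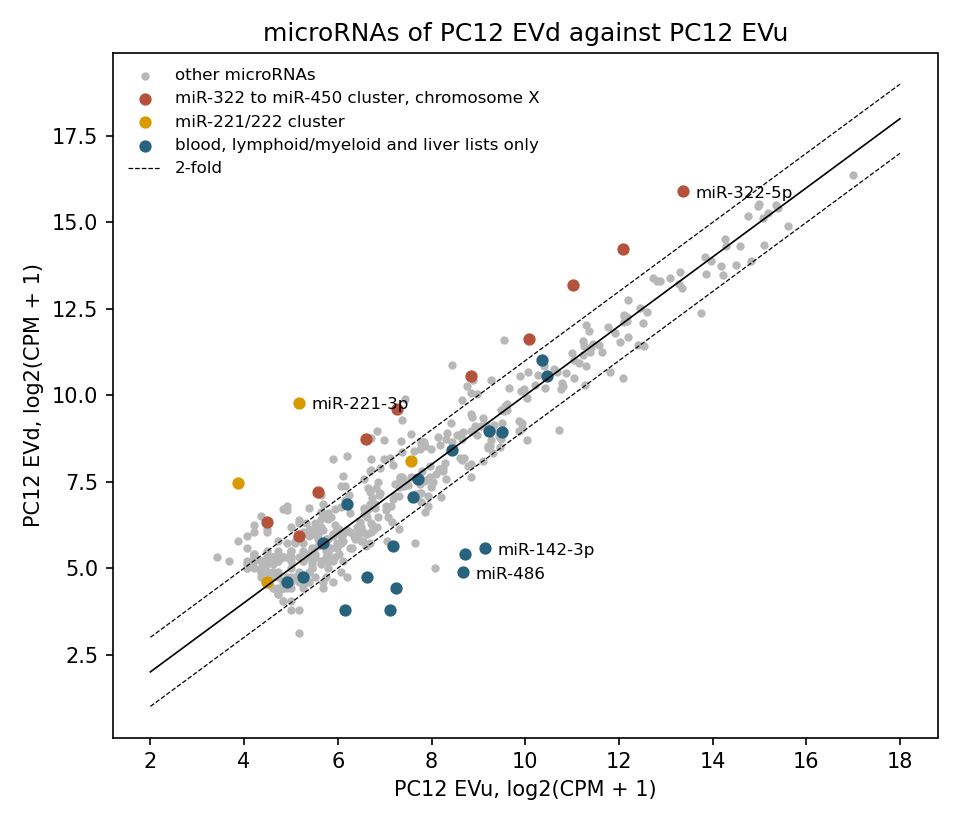
Each point is 1 of 472 microRNAs, placed by log2(CPM + 1) in PC12 EVu and in PC12 EVd, with 1 library each; the solid line marks equal values and the dashed lines a fold of 2. The cluster of miR-322 lies above the upper line except miR-450b-3p at 0.74, and miR-486 at -3.80 lies far below the lower line.

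RMT1 EVs carried epithelial microRNAs such as miR-200c-3p and miR-205 that had few counts in PC12 EVs, and had few or no counts of miR-375-3p, miR-9a-5p and most of the Hox cluster microRNAs that PC12 EVs carried. The exception was miR-10a-5p of a Hox cluster, with 61 and 56 counts in RMT1 against 5959 in EVu and 3399 in EVd. miR-200c-3p, which keeps epithelial cells epithelial by repressing Zeb1, and miR-205, of basal epithelium, were higher in RMT1 by 9.90 ± 0.11 (SE, limma adjusted p = 0.00413) and 10.13 ± 0.12 (adjusted p = 0.00443) on the log2 scale, with 2 RMT1 libraries against 1 each of EVu and EVd. By library totals the ratios of pooled shares were lower, at 342 (191 to 685) and 299 (171 to 579), from 11 and 12 counts in PC12. Of 12 tested names of the epithelial list, 10 were higher and 2 lower in RMT1, and also when adjusted over the list alone (percentile 100). The 2 lower ones, miR-192-5p and miR-194-5p, belong to liver and gut epithelium and lay close to the threshold. In the other direction, miR-375-3p, a microRNA of endocrine cells, had 0 counts in both RMT1 libraries and 2899 and 1023 in EVu and EVd, so it was at least 803-fold lower in RMT1 in the authors' scaling, and at least 2557-fold by library totals. miR-9a-5p, a neural microRNA, was at least 702-fold lower, and 2049-fold by library totals. Some PC12 names at 0 in the table of all 4 libraries had many counts in the PC12 table. RMT1 has no second table to check its 0 counts, so these bounds are uncertain. limma called 92 of 278 microRNAs higher and 103 lower in RMT1 at an adjusted p of 0.05. Part of the 103 had 0 counts in both RMT1 libraries, which sets their spread to 0 and makes the limma error very small. An example is miR-451-5p, with 38 and 2 counts in EVu and EVd (limma adjusted p = 0.000339). Such calls do not rest on a measured spread. These names also entered the mean-variance trend and the prior that limma used for all 278 microRNAs.

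The 12 largest folds upward were led by miR-31a-5p, with 49309 and 46967 counts in RMT1, 3 in EVu and 0 in EVd, a ratio of pooled shares of 16406 (counting interval 5614 to 79554). In the PC12 table it had 34 and 42 counts, so the size of this ratio is uncertain. They included miR-206-3p, of skeletal muscle, with 1 and 6 counts in PC12 and a ratio of 404 (196 to 1005), and miR-34a-5p and miR-449a-5p, of a family activated by p53, at ratios of 82.0 (57.7 to 121) and 150 (58.3 to 550). miR-28-3p had 1057 and 914 counts in RMT1 and 3 in PC12, a ratio of 336 (115 to 1630). miR-155-5p, a microRNA of activated lymphocytes that is raised in many tumours, had 4 counts in PC12 and a ratio of 80.1 (31.1 to 295). miR-466c-5p, miR-466b-5p and miR-200a-5p had 0 counts in both PC12 libraries and were at least 254-fold, 117-fold and 42.9-fold higher by library totals. The PC12 table does not list them, but there miR-466b-3p of the same cluster had 26 and 8 counts against 0 in the table of all 4 libraries, so these bounds are uncertain. miR-222-5p had 356 and 209 counts in RMT1 and 0 in PC12, but 96 and 106 counts in the PC12 table, so no bound is given.

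The 12 largest folds downward included miR-152-3p, with 0 counts in RMT1 and 2683 and 2223 in PC12, at least 1139-fold lower in the authors' scaling and 3199-fold by library totals, and miR-10a-3p, at least 112-fold and 322-fold lower. These bounds are uncertain too, since the 0 counts of RMT1 cannot be checked in a second table. miR-10b-5p, a Hox cluster microRNA studied in breast cancer invasion, had 2 counts in RMT1, a ratio of pooled shares of 5797 (1604 to 47879); its PC12 counts of 3631 and 2296 were 606 and 483 in the PC12 table. miR-196c-5p, also from a Hox cluster, had 1 count (ratio 2361, 423 to 93334). The neuronal microRNAs miR-218a-5p and miR-129-5p were lower, miR-218a-5p by -9.19 ± 0.82 (limma adjusted p = 0.0318), and miR-129-5p with 2 counts in RMT1 at a ratio of 886 (245 to 7328). miR-384-5p had 6 counts in RMT1 and a ratio of 1338 (614 to 3649). miR-101a-3p, miR-672-5p and miR-384-3p had 4 counts each in RMT1, with ratios of pooled shares of 1809 (706 to 6643), 1192 (465 to 4378) and 922 (359 to 3387).

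By list, all 8 Hox cluster names were lower in RMT1 (percentile 0.05), and of 11 names of the mesenchymal list 8 were lower and 2 higher (percentile 0.26), 4 of these being Hox cluster names. miR-27b-3p of that list was at -6.90 ± 0.04 (limma adjusted p = 0.00217). The neuronal list still held 0.844% ± 0.0717 (SD, n = 2) of RMT1 counts, against 8.73% of EVu and 9.50% of EVd. Of its 18 tested names 13 were lower, 1 higher and 4 not called, and 16 were lower and 2 higher when adjusted over the list alone (percentile 5.08, or 12.3 with names at 0 in 1 cell line placed at their bound). In the let-7 family 9 of 15 names were higher, 3 lower and 3 not called, and the same counts held when adjusted over the list alone (percentile 96.2). The 9 are the abundant arms, such as let-7c-5p at 3.69 ± 0.09 (SE, limma adjusted p = 0.00943), let-7b-5p at 3.85 ± 0.11 (adjusted p = 0.0103) and let-7g-5p at 5.13 ± 0.08 (adjusted p = 0.00636). All of the 9 stayed above 0 when scaled by library totals, but at smaller values, from 0.11 for let-7e-5p to 3.64 for let-7g-5p. There let-7c-5p was at 2.19 and let-7b-5p at 2.36. Of 12 names of the breast tumour list 8 were higher and 4 lower (percentile 98.2), with miR-21-5p at 2.69 ± 0.06 (limma adjusted p = 0.00828). The 3 tested names of the miR-466 cluster of the Sfmbt2 gene stood at percentile 99.9, 2 of them higher. For the epithelial, Hox, mesenchymal and breast tumour lists the counts were the same when adjusted over the list alone. With names at 0 in 1 cell line placed at their bound, the percentiles were 100 for the epithelial list, 0.105 for the Hox clusters, 0.175 for the mesenchymal list, 98.2 for the breast tumour list and 99.9 for the Sfmbt2 cluster. Of 24 lists with tested names, 5 lay outside the central 95%, where 1.20 would by chance if names varied independently, which names of 1 cluster need not do.

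**Figure D3:**
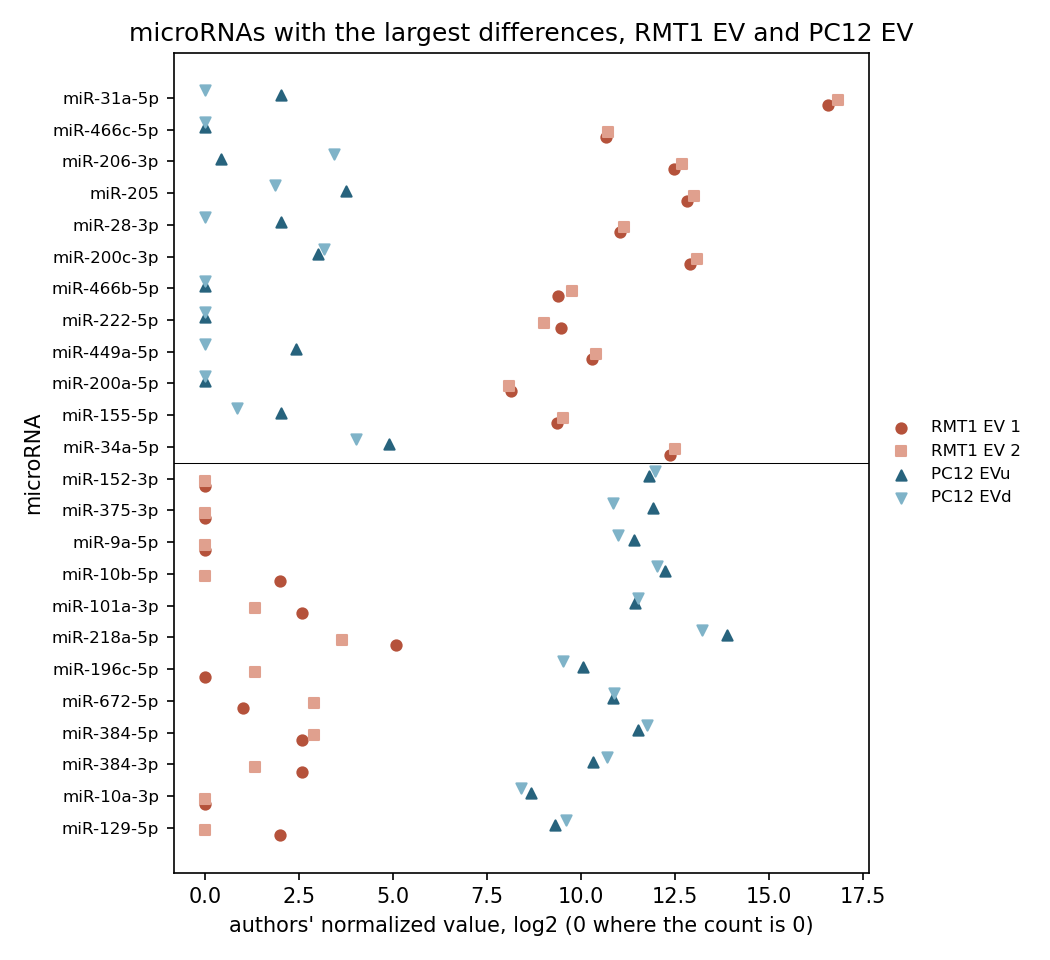
Points give the authors' log2 normalized value of each library, with 0 where the count is 0, for the 12 microRNAs with the largest folds each way between RMT1 EV (2 libraries) and PC12 EV (EVu and EVd, 1 library each). The RMT1 libraries lie close together for the upward microRNAs and further apart for several downward ones, such as miR-10b-5p with 2 and 0 counts, and miR-31a-5p, with 49309 and 46967 counts in RMT1, reaches the highest value.

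The balance of the calls changed with scaling by library totals, with the test and with the spread taken from 1 pair of libraries. Scaled by library totals, of which let-7 takes so much in RMT1, the median log2 difference of all tested microRNAs moved from -1.12 to -2.54 and limma called 64 higher (30.6% of calls) and 145 lower, against 47.2% higher in the authors' scaling. Other scalings kept that balance. limma called 94 higher and 105 lower with TMM (47.2% higher), and 92 and 97 with totals that leave out let-7 (48.7% higher). Without RMT1 library 1, and with EVu and EVd as 1 group, 56 were higher and 99 lower, without library 2 there were 53 and 95, and edgeR with TMM on the recovered counts called 97 higher and 157 lower.

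The authors' own tables give folds without a test. In the authors' deposited table of EVd against EVu, 87 of 594 names were at least 2-fold higher and 73 at least 2-fold lower. The 5 highest there were miR-221-3p (log2 4.62), miR-222-3p (3.66) and 3 piRNA names, and the 5 lowest were miR-486 (-3.88), miR-142-3p (-3.63), miR-451-5p (-3.43), miR-223-3p (-3.37) and miR-18a-3p (-3.32). In the authors' deposited table of the PC12 mean against the RMT1 mean, 215 of 762 names were at least 2-fold higher in PC12 and 119 at least 2-fold lower. Its extremes were miR-31a-5p (-15.70), miR-466c-5p (-10.68), miR-206-3p (-10.65), miR-205 (-10.13) and miR-28-3p (-10.09) below, and miR-152-3p (11.89), miR-375-3p (11.38), miR-9a-5p (11.19), miR-10b-5p (11.13) and miR-335 (10.93) above. miR-335 shows why single pairs matter: it had 5 counts in RMT1 library 1 and 0 in library 2, and did not pass limma (adjusted p = 0.0643). In the authors' deposited tables of single libraries, the number at least 2-fold higher in PC12 ran from 193 for EVd against RMT1 library 2 to 215 for EVu against RMT1 library 1.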

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

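The PC12 table also lists 66 piRNA names, which enter the authors' counts of names above and no comparison of microRNAs. They held 3.30% of EVu counts (95% exact binomial interval 3.25% to 3.35%) and 2.79% of EVd counts (2.73% to 2.84%), far above the 0.000586% and 0.000775% that a count of 0 allows. Of 56 piRNA names with a mean of at least 10 counts, 15 were at least 2-fold higher and 9 at least 2-fold lower in EVd. The 2 most counted names held 48.6% of the piRNA counts in EVu and 34.7% in EVd. No explanation of these counts was tested.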

How the results depend on the processing

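Alternatives that use the other deposited table, counting intervals, lists left out, single PC12 libraries or other limma scalings were chosen after seeing the data. edgeR with TMM was the test planned for raw counts. Its use on recovered counts, and limma as the main test, were chosen after the data were seen. All 24 named microRNAs of EVd against EVu kept their direction and a fold of 2 under 5 other pseudocounts and scalings. In the table of all 4 libraries 16 of 24 did, 6 had under 3 counts, miR-192-3p was at -0.99 and miR-874-5p reversed to -0.50; the cause was not tested. The counts of 65 higher and 33 lower became 24 and 13 with a minimum mean of 100 and 16 and 8 at a fold of 4, as stricter rules must give. They were 23 and 14 where the whole counting interval lay beyond a fold of 2. Without a minimum 54 were lower, 26 were higher and 32 lower in the other table (44.8% higher, against 66.3%), and without the blood, lymphoid and liver lists 21 were lower.

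The median absolute log2 difference of the RMT1 libraries was 0.35 without a minimum. Between cell lines 192 were lower without a filter, where 440 names were tested, and 157 with edgeR and TMM. On the same recovered counts limma with TMM called 105 lower, DESeq2 107, and edgeR with DESeq2 size factors 147. Among these the larger number went with edgeR and not with TMM. Scaled by library totals, however, limma also called 145 lower. Why edgeR called more was not tested. Leaving out 1 RMT1 library gave 53 to 56 higher, with the lone library assumed to vary like the PC12 pair. Against EVd alone limma called 85 higher and 89 lower, and against EVu alone 82 and 90. All 24 named microRNAs kept their direction under 13 alternatives, but miR-672-5p, miR-129-5p, miR-10b-5p and miR-196c-5p did not pass the threshold in some. At a fold of 4, 25 names were higher and 13 lower in EVd in the authors' deposited values. The let-7 share was 20.8% of EVu and 19.5% of EVd in the PC12 table, which includes piRNA names in its totals. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Depth limits microRNAs near 3 counts, whose counting intervals are wide.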

Other observations

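Other families differed less between EVd and EVu. In the Dlk1-Dio3 cluster, an imprinted cluster active in brain and neuroendocrine tissue, 23 of 34 names were above 0 and 4 at least 2-fold higher (percentile 95.3), with miR-127-3p at 0.57 (0.37 to 0.76) and miR-379-3p at -0.73 (-1.03 to -0.44). These values depended on the table, since miR-127-3p had 411 and 460 counts in the PC12 table but 21 and 1 in the other, where the cluster stood at percentile 6.60. The clusters of miR-23, miR-27 and miR-24 stood at percentile 95.5, the miR-29 family at 91.5 and the neuronal list at 85.9, where miR-125b-5p at 0.54 and miR-218a-5p at -0.72 went apart. The muscle list stood at percentile 88.1, the breast tumour list at 85.3 and the miR-183 cluster at 80.7. The let-7 family (percentile 53.5), the miR-181 family (48.4), the miR-34 family (42.8), the mesenchymal list (28.2) and the miR-17 clusters (23.0) had medians within 0.1 of 0. The miR-17 clusters stood at 0.465 with a minimum mean of 100 and at 1.48 in the other table, and the clusters of miR-23 at 99.3 with that minimum. The embryonic miR-290 clusters (22.2), the neuroendocrine (14.9) and epithelial (14.7) lists, hypoxia (11.1), the Hox clusters (10.5) and the Sfmbt2 cluster (5.37) lay inside the central range.

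Between cell lines, 4 of 6 names of the miR-29 family were lower in RMT1 and 2 were not called. miR-29c-3p was at -7.97 ± 0.04 (SE, limma adjusted p = 0.00169) and miR-29a-3p at -1.23 ± 0.22 (adjusted p = 0.0660), so the values in this family, which represses collagen genes, were uneven. How reads were split between similar members was not tested, here or for miR-27b-3p, and RMT1 has no second table. All 3 names of the miR-34 family and both muscle names were higher in RMT1. The 4 names of the cluster of miR-221 and miR-222 were called higher than the PC12 mean. By share the cluster held 0.114% ± 0.00513 (SD, n = 2) of RMT1, 0.101% of EVd and 0.00252% of EVu. In the PC12 table it held 0.135% of EVd, which is not below RMT1, and 0.0258% of EVu. Both miR-222-5p and miR-221-5p depended on the table. miR-221-5p had 0 and 3 counts in EVu and EVd, but 11 and 9 in the PC12 table. Of 11 neuroendocrine names 7 were lower and 1, miR-183-3p, higher. Of 14 names of the miR-17 clusters 7 were higher and 2 lower, but 5 were above 0 when scaled by library totals against 10 in the authors' scaling. The calls in the other lists, higher first, were 5 and 3 of 12 for blood and serum, 3 and 3 of 8 for lymphoid and myeloid, 1 and 2 of 3 for liver, 2 and 6 of 10 for the miR-16 family, 4 and 4 of 11 for miR-30, 2 and 3 of 8 for miR-23, miR-27 and miR-24, 1 and 2 of 6 for miR-181 (0 and 0 when adjusted over the list alone), 1 and 3 of 4 for miR-183, and 8 and 4 of 19 for the neurotrophin list. The hypoxia list had 1 name, higher, and the miR-290 clusters 1, lower; no name of the Dlk1-Dio3 cluster was tested. Scaled by library totals, the liver microRNA miR-122-5p moved from 1.13 to -0.36, and fewer names were above 0 in the blood list (5, from 8), the miR-30 family (2, from 5) and the clusters of miR-23 (1, from 5).

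Of the tests below, all but that of neighbouring hairpins were chosen after the result was seen, and those of scaling and of a single source replaced earlier tests that could not decide. Part of the blood and liver microRNAs were lower in EVd: the 19 names that only the blood, lymphoid and liver lists hold, both arms of miR-122 being the liver ones, had a median of -0.55, with 11 intervals below 0, 1 above and 7 that included 0. Scaling by 1 factor per library moves every microRNA alike, and the median of these names lay -0.62 from that of the 453 others (percentile 0.15 of random sets), which argues against scaling as the whole source. A smaller share of serum or blood RNA from 1 source would lower miR-451, miR-144, miR-486, miR-122, miR-223 and miR-142 by 1 ratio. Per degree of freedom, the chi-square of their ratios was 1.64 times that between the RMT1 libraries in the PC12 table and 0.772 times in the other. The RMT1 value covers names with far more counts, which can raise it, so this test cannot decide on 1 source. The ratios differed by more than counting error, with a chi-square of 89.7 over 9 names in the PC12 table and 31.7 over 7 in the other. Serum or blood RNA, or PC12 cells making some of these microRNAs, may account for the lower values, and what u and d stand for remains an untested biological explanation.

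The cluster of miR-322 on chromosome X was higher in EVd by a median of 1.95 more than the 462 other microRNAs. Scaling by 1 factor per library cannot change this gap. The cluster was picked after its high ratios were seen, so a large gap was sure to be found and is not an independent test of scaling. In the other deposited table the cluster was also higher, with a median of 2.24 over 9 names. The counting behind the PC12 table is therefore not a likely source of the higher values. A difference between the PC12 cells or in how their vesicles are loaded stays open as a hypothesis, with 1 library per group.

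A hypothesis fixed before its result was seen was that neighbouring hairpins, which often share a primary transcript, shift together between EVd and EVu. With the miR-322 and miR-221 clusters left out, 71 neighbouring pairs within 10 kb among 288 hairpins differed by 0.67 on average, against 0.93 for permuted values (1-sided permutation test, p = 0.00107). This is what shared transcripts would give, but near-identical members of 1 cluster that share reads could add to it, which was not tested. Many of the paired hairpins lie in the Dlk1-Dio3 cluster, whose values depended on the table, and only the PC12 table was used here.

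The let-7 share of RMT1 exceeded the highest PC12 share by at least 45.9 percentage points as a family sum, which reads moved between let-7 members cannot change. By library totals, miR-451, miR-144, miR-486, miR-122, miR-223 and miR-142 together reached at most 0.526 times the lowest PC12 level in RMT1. Let-7 itself swells the RMT1 totals, and the counts of these microRNAs were 51 and 41 in RMT1, 759 in EVu and 41 in EVd. Among them miR-122-5p was at 1.13 in the authors' scaling and -0.36 by library totals. This comparison therefore does not settle whether serum RNA contributed. miR-320-3p and miR-423-5p of the blood list were higher in RMT1 by 5.08 and 4.87 in the authors' scaling, and by 3.58 and 3.38 by library totals. A part from serum stays open. A difference between the cell lines stays as a hypothesis, since it was found and tested on the same libraries.

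Of names in the PC12 table that lie opposite another listed microRNA on the other strand, 52.1% were at 0 in the table of all 4 libraries, against 25.6% of other names (Fisher's exact test, 2-sided, p = 0.000285, across names, which are not replicates).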
